A study of Danio rerio with 2 samples.

How the data were processed

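ATAC-seq was done on 2 zebrafish melanoma cell lines, zcrest 1 and zcrest 2, with 1 library of 50000 cells each. Cells were lysed and treated with the transposase, and libraries were built by the original ATAC-seq procedure, per the labels' protocols. One peak list per library was used. Peaks were called with MACS2 2.1.0 on the genome build Zv9, per the submitters' processing notes. The peak names in each deposited list carry that library's own name, so peaks were called per library and not on pooled reads. The aligner, the handling of duplicate reads, the shift of reads for the transposase and the total read number are not given in the sources used here.

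Each deposited list gave the position of every peak, a score, a fold enrichment, a -log10 p, a -log10 q and a summit offset. These values are the authors' own and were used to describe, rank and filter peaks within a list. The deposited score equals 10 times the -log10 q with the decimals dropped, in all peaks but 1. The deposited fold enrichment is the ratio of the summit pileup plus 1 to the local background plus 1. The deposited -log10 p is that of a Poisson test of the pileup against the same background, and the deposited -log10 q is the same after the peak caller's correction for multiple tests, by the usual layout of such lists. The lowest -log10 q was 1.31 in zcrest 1 and 1.32 in zcrest 2, which is a q-value threshold of 0.05 in the authors' lists. The deposited summit offset counts from 0 at the peak start. Positions are given here counted from 1.

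The fold enrichment and the -log10 p depend on the same 2 quantities, so both equations were solved for each peak by trying every whole-number pileup up to 800. A pileup that met the deposited -log10 p within 0.001 was found for 100% of the peaks of both lists, and the largest error was 0.000131. The local backgrounds so obtained were whole multiples of what 1 read of 200 bp adds to a window of 10000 bp, or the genome-wide value, within 0.02 reads, in all peaks of zcrest 1 and all but 1 of zcrest 2. This window holds the peak's own reads too, so a strong or wide peak raises its own local background. The genome-wide value, below which no peak lay, was 1.57 in zcrest 1 and 2.01 in zcrest 2. It is proportional to the number of reads used, and 22.3% and 19.8% of the peaks lay at it. No pileup exceeded 391, under the 400 that 1 read per position and strand allows at a length of 200 bp. The highest, 379 to 391, were on the mitochondrial genome, where enrichment was 1.19-fold to 2.05-fold. On the numbered chromosomes the highest pileups were 299 and 340.

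Before the data were examined, the following choices were made: the comparisons of peak number, overlap, overlap by strength, rank correlation, peaks of a single line and clusters, their tests and most of the other settings tried. Peaks were counted as shared when at least 1 bp overlapped. Overlap was compared with 1000 circular shifts of one list along each chromosome (one-sided permutation test). Shares carry exact (Clopper-Pearson) binomial intervals of 95%, which cover counting error only. Strength was divided into 10 equal classes of -log10 q within each list. Peaks of a single line had no peak of the other list within 1 kb. Their split over the 25 numbered chromosomes was tested by Fisher's exact test, two-sided, each chromosome against the rest, with Benjamini-Hochberg adjustment at 0.05. Clusters joined peaks within 12.5 kb, and the top 200 by summed fold enrichment were compared with shifted lists. The named regions follow 1 rule: the 5 peaks of highest -log10 q of each line, the 5 highest of each line with no peak of the other list within 1 kb, and the 5 clusters with most peaks of each line. Chromosomes and 5-Mb windows named in the text, the group of 1000 strongest peaks and the stretches named in the closing observations were chosen after their values were seen.

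The ratio of pileups between the lines was added after the data were examined. It was the median log2 ratio of zcrest 2 over zcrest 1 across peaks matched one to one, minus the median over the genome, per chromosome and per window of 5 Mb with at least 20 pairs. The SE came from bootstrap draws of the pairs, 1000 per chromosome and 500 per window. Background ratios used the 75th percentile. Windows of 500 kb with at least 5 peaks in a line were called raised where the median background of that line was at least 3 times its median over the genome.

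The scripts were tested on simulated data before use. Pileups were recovered exactly in 99.98% of 4964 simulated peaks like those of zcrest 1 and in 99.96% of 4947 like those of zcrest 2. An unrelated list the size of zcrest 1 overlapped zcrest 2 at 0.985 times the shifted mean (permutation p = 0.79), and a planted overlap of 29.9% came back as 29.9%. With no difference planted, 0 chromosomes passed the chromosome test. With a loss of 30% planted on 3 chromosomes, those 3 passed and 0 others did. Both sets of these 2 checks were random draws from the zcrest 1 list. They lacked the runs that real peaks of a single line form, so the checks do not give the error rate of the test on real peaks. A log2 shift of 1 planted in the pileups of chromosome 16 came back as 1.03. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

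The other settings fixed at that point were other definitions of a shared peak, thresholds of -log10 q of 5 and 10, lists of equal length, the mitochondrial peaks left out, local shifts, ranking by fold enrichment, other distances for peaks of a single line and other rules for clusters. Settings added later were leaving out the raised windows and, for the pileup ratio, using only pairs with at least 60 reads in total or using the local background. The planned annotation of peaks, gene lists and sequence motifs were left out. They need a genome sequence and annotation of Zv9, which were not used here, and positions were not converted between builds. Gene tables of a later assembly were set aside for the same reason: on chromosome 4, for example, its last gene ends at 76373753 and the last peak at 62066129.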

Results

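Open chromatin was mapped by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in 2 independent zebrafish melanoma cell lines, zcrest 1 and zcrest 2. Both lines carried the same listed background of p53 and BRAF alterations, the reporter crestin:EGFP and the MiniCoopR vector alone, and had passed more than 20 passages. The genotype label also holds the abbreviation Na, which was not expanded here. The crestin reporter marks neural crest cells, the embryonic population from which melanocytes arise, and MiniCoopR is a vector that restores melanocytes through a copy of mitfa. Each line was represented by 1 library from 50000 cells, so there were no replicates, and every comparison is between 2 libraries and not between lines in general. The title of the series concerns neural crest identity in melanoma. The question the 2 lists can address here is which accessible regions the lines shared and which were called in a single line. Positions are in the zebrafish build Zv9 and no gene is named, because no annotation of that build was used here.

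In zcrest 1, 63335 accessible regions were called, against 53132 in zcrest 2. They covered 27.9 Mb and 23.4 Mb. All but 3 regions in each line, which lay on the mitochondrial genome, were on the 25 numbered chromosomes. The median region was 397 bp wide in zcrest 1 and 387 bp in zcrest 2. Chromosome 19 held the most regions in zcrest 1 (3774), and chromosome 5 the most in zcrest 2 (3275). Chromosome 4 held the fewest in zcrest 1 (1672) and chromosome 15 the fewest in zcrest 2 (1077). The median summit stood on 18 overlapping reads in zcrest 1 and on 19 in zcrest 2, and the median enrichment over the local background was 5.79-fold and 5.03-fold. The genome-wide background was 1.57 reads in zcrest 1 and 2.01 in zcrest 2, a ratio of 1.28. Numbers of regions move with depth and with background, and with 1 library per line the difference in number was not tested.

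More accessible regions were shared between the lines than were private to either. Of the regions of zcrest 1, 34661 overlapped a region of zcrest 2 by at least 1 bp, or 54.7% (95% exact binomial interval 54.3% to 55.1%). Of the regions of zcrest 2, 34495 overlapped a region of zcrest 1, or 64.9% (64.5% to 65.3%). When one list was shifted along each chromosome at random, 3.48% of the regions of zcrest 1 and 4.15% of those of zcrest 2 overlapped the other list, so the observed overlap was 15.7 and 15.6 times the shifted mean. None of 1000 shifts reached the observed number (permutation test, one-sided p = 0.001 for each line, the smallest that 1000 shifts can give). The overlap covered 14.5 Mb, 39.3% of the 36.8 Mb that either line had in its list. The intervals cover counting error only, and the shifts show only that the lists overlapped more than unrelated positions would. The share depended on what was counted as shared: with summits required to lie within 100 bp of each other it was 41.3% and 49.3%.

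Regions of strong signal were shared far more often than weak ones. In zcrest 1 the weakest decile of regions, ranked by the deposited -log10 q, overlapped zcrest 2 in 24.6% of cases (23.5% to 25.7%) and the strongest decile in 88.3% (87.5% to 89.1%). In zcrest 2 the share rose from 27.6% (26.4% to 28.9%) in the weakest decile to 97.1% (96.6% to 97.5%) in the strongest. It rose at every step between, in both lines. Of the 1000 strongest regions, 93.8% in zcrest 1 (92.1% to 95.2%) and 98.6% in zcrest 2 (97.7% to 99.2%) had a counterpart in the other line. The weakest decile rested on a median of 9 reads at the summit in zcrest 1 and 11 in zcrest 2, so at this depth a missing counterpart of a weak region does not show that the region was closed.

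**Figure D1:**
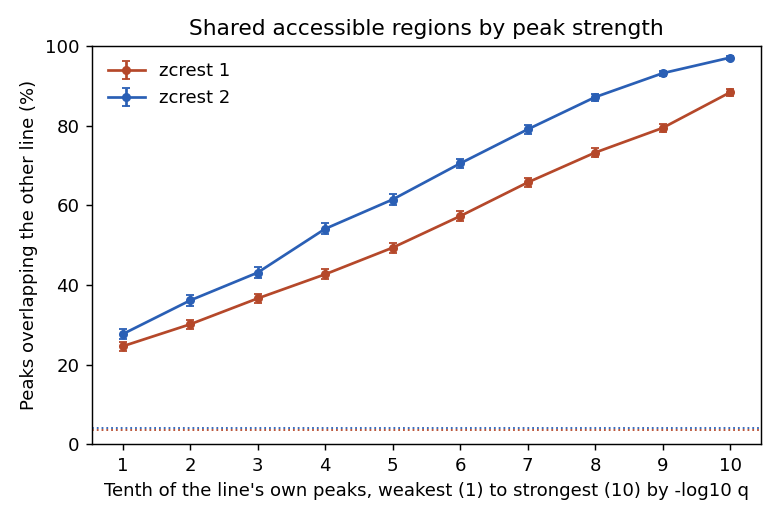
Share of each line's accessible regions (y axis, percent) that overlapped a region of the other line, by decile of -log10 q within the line's own list (x axis, weakest at 1 and strongest at 10); bars are 95% exact binomial intervals and dotted lines the mean of shifted lists. The share rose from 24.6% to 88.3% in zcrest 1 (red) and from 27.6% to 97.1% in zcrest 2 (blue), against 3.48% and 4.15% for shifted lists.

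Where both lines had a region, the summits mostly lay close together. Among 32456 regions matched one to one, the median distance between the summits was 31 bp. Of the summits, 62.1% lay within 50 bp of each other and 77.1% within 100 bp. Matching required overlap, which by itself keeps summits near, and no expected distance was computed. The lists ranked these regions similarly, with a Spearman rho of 0.61 for fold enrichment, computed across regions, which are not independent replicates. The median pair had 24 reads at the summit in each line. Fold enrichment was higher in zcrest 1 in 66.0% of the pairs, with medians of 6.99 in zcrest 1 and 5.97 in zcrest 2, and the median ratio of summit reads, zcrest 2 over zcrest 1, was 1.06.

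The single strongest region was the same in both lines. It lay on chromosome 20 at 4645199 to 4645768 in zcrest 1, where 175 reads stood at the summit, and at 4645201 to 4645772 in zcrest 2, where 231 did. The enrichment was 20.7-fold and 23.5-fold. The next strongest regions of zcrest 1 were on chromosome 2 at 19015285 to 19016069, chromosome 5 at 64236648 to 64237229, chromosome 2 at 13838703 to 13839329 and chromosome 20 at 6555446 to 6557178. Their -log10 q ran from 143 to 151, and in zcrest 2 they ranked 14, 15, 13 and 8. In zcrest 2 the next strongest were on chromosome 15 at 45149309 to 45150427, chromosome 11 at 35982396 to 35983194, chromosome 6 at 43357400 to 43358157 and chromosome 2 at 135016 to 135777. The chromosome 15, 11 and 6 regions ranked 8, 7 and 10 in zcrest 1. The region near the start of chromosome 2 stood apart from them: it ranked 803 in zcrest 1, with 108 reads at the summit against 216 in zcrest 2. The regions on chromosome 2 at 19015285 and on chromosome 20 at 6555446 had a local background 12.2 and 15.4 times the line's median, so their enrichment was lower than their read number alone would give. That background includes the reads of these regions themselves, so by itself it does not show a raised level around them.

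Each line also had strong regions with no called region of the other line nearby. With a distance of more than 1 kb to any region of the other line required, 26360 regions (41.6% of those on the numbered chromosomes) were found in zcrest 1 alone and 16343 (30.8%) in zcrest 2 alone. Most were weaker than shared regions. Their median summit had 14 reads in both lines, where shared regions had 24, and their median width was 323 bp and 286 bp against 469 bp and 459 bp. A -log10 q of at least 10 was reached by 7033 of the regions of zcrest 1 alone (26.7%) and by 2157 of those of zcrest 2 alone (13.2%). Among shared regions 62.3% and 55.9% reached it, and in the whole lists 29005 of 63335 and 21705 of 53132. The score ranks regions within a list, so the same cut is not equally strict in both lines.

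The 5 strongest regions of zcrest 1 alone lay on chromosomes 3, 2 and 15. The strongest, on chromosome 3 at 47628943 to 47629439, had 157 reads at its summit, a 14.1-fold enrichment and a -log10 q of 119, and the nearest region of zcrest 2 lay 17.8 kb away. The next were on chromosome 3 at 47399460 to 47400147 and at 51187067 to 51188255, on chromosome 2 at 21895362 to 21896329 and on chromosome 15 at 38279154 to 38279978, with 190, 160, 162 and 130 reads at their summits. The local background at these 5 regions, which counts each region's own reads, was 4.56 to 10.2 times the median of zcrest 1. Of the 7033, 123 (1.75%) lay in the 500-kb windows whose background was at least 3 times the median in zcrest 1 alone, which held 0.797% of all regions of zcrest 1. The strongest regions of zcrest 2 alone were more spread out. Their local background, own reads included, was 1.40 to 3.75 times the line's median, with fewer reads at the summits, 77 to 113. They were on chromosome 22 at 37511513 to 37512444, chromosome 5 at 4555757 to 4557014, chromosome 13 at 53793102 to 53793925, chromosome 17 at 15712738 to 15713373 and chromosome 22 at 9737301 to 9738198. The first of them had 94 reads at its summit, a 14.0-fold enrichment and a -log10 q of 73.3, and the nearest region of zcrest 1 lay 32.4 kb away. Whether a region was closed in the other line or only below the calling threshold could not be separated, because read numbers outside called regions were not analysed here.

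Regions found in a single line were distributed unevenly over the chromosomes. Chromosome 16 held 1547 regions of zcrest 1 alone and 207 of zcrest 2 alone, an odds ratio of 4.86 relative to the other chromosomes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 2.41e-139). Chromosome 12 went the other way, with 524 of zcrest 1 alone and 1062 of zcrest 2 alone (odds ratio of zcrest 2 over zcrest 1 3.43, adjusted p = 1.86e-121 by the same exact test). Chromosomes 15, 23, 19 and 9 also leaned to zcrest 1, with odds ratios of 3.04, 2.54, 2.22 and 2.09. Chromosomes 18, 1 and 13 leaned to zcrest 2, with odds ratios of 2.53, 2.30 and 2.25. In all, 23 of 25 chromosomes passed the test, 12 towards zcrest 1 and 11 towards zcrest 2, and chromosomes 6 and 14 did not. The direction is relative to the other chromosomes, so a near-even split is partly built in. Chromosomes 4, 5, 8, 10 and 24 passed towards zcrest 2 but held more regions of zcrest 1 alone, 915 against 684 on chromosome 4. The test compares these 2 libraries and takes regions as independent, which neighbouring regions are not. With a -log10 q of at least 10 required, 16 chromosomes passed, and the odds ratio of chromosome 25 turned from 1.20 to 0.886 and no longer passed.

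The number of reads at regions that both lines shared differed along the same chromosomes. On chromosome 16 the median summit had 0.682 times the reads in zcrest 2 that it had in zcrest 1, with the genome-wide median set to 1 (log2 ratio -0.55, bootstrap SE 0.02, 1020 pairs), and reads were higher in zcrest 2 than this median ratio at 20.5% of the pairs. On chromosome 12 the ratio was 1.44 (log2 ratio 0.53, bootstrap SE 0.02, 1151 pairs), with 79.0% of the pairs above the median ratio. Chromosomes 23, 19 and 15 had log2 ratios of -0.47, -0.47 and -0.30. Chromosomes 18, 13, 1, 22 and 11 had log2 ratios of 0.36, 0.29, 0.29, 0.29 and 0.28. Of the 25 chromosomes, 11 lay above and 11 below the genome-wide median by more than 2 bootstrap SE. This comparison was added after the lists had been examined, and the bootstrap SE covers the spread between regions of 1 library pair only. On chromosome 7 the log2 ratio was -0.08 and turned to 0.09 when only pairs with at least 60 reads in total were used.

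In windows of 5 Mb the differences began and ended inside chromosomes. On chromosome 11 the 6 windows from 0 to 30 Mb had log2 ratios of 0.30 to 0.64 and the 4 windows from 30 to 50 Mb had ratios of -0.31 to -0.19. On chromosome 19 the windows from 0 to 20 Mb lay at -0.91 to -0.75, and the next, from 20 to 25 Mb, at -0.40. On chromosome 7 the windows from 25 to 45 Mb lay at -0.93 to -0.55, and the window from 55 to 60 Mb at 0.44. On chromosome 5 the windows from 60 to 80 Mb lay at 0.53 to 0.64, and the window from 50 to 55 Mb at -0.67. The windows of chromosome 16 were all below 0 and those of chromosome 12 all above 0. The lowest of the 279 windows, chromosome 15 from 35 to 40 Mb, had a log2 ratio of -1.11 (bootstrap SE 0.16, 94 pairs) and held 296 regions of zcrest 1 alone against 20 of zcrest 2 alone. The highest, chromosome 22 from 5 to 10 Mb, had a log2 ratio of 0.74 (bootstrap SE 0.07, 111 pairs), with 49 regions of zcrest 1 alone and 96 of zcrest 2 alone. Above a log2 ratio of 0.5 lay 25 windows, and below -0.5 lay 32.

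**Figure D2:**
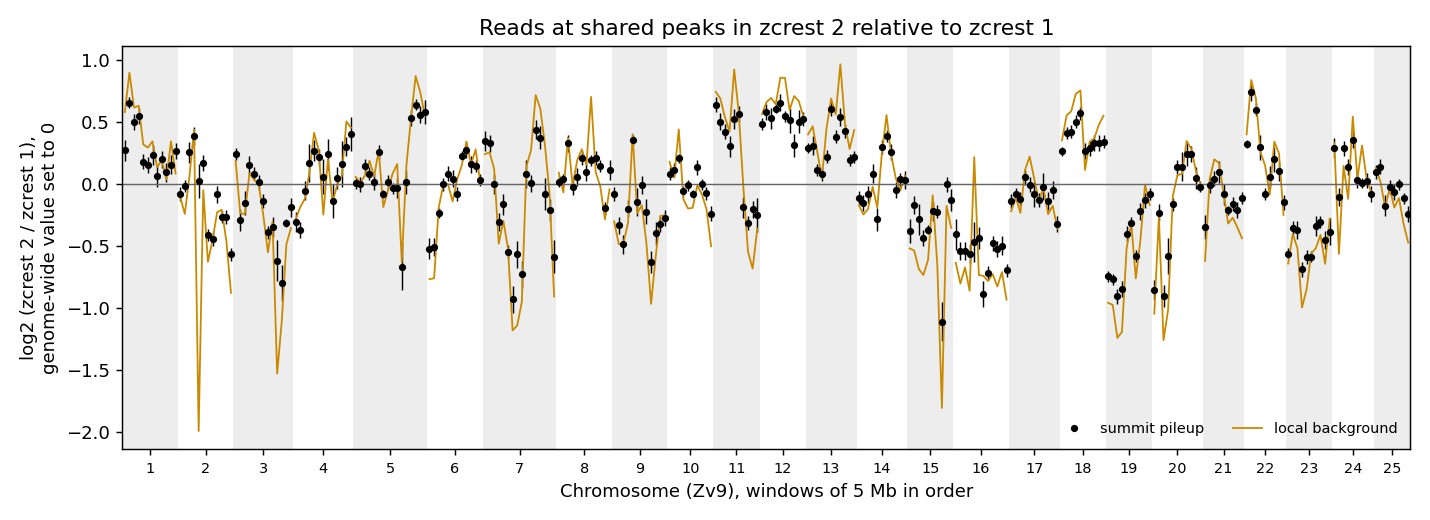
Log2 ratio of zcrest 2 over zcrest 1 (y axis, genome-wide value set to 0) in consecutive 5-Mb windows of the 25 chromosomes (x axis): points are the median of summit reads at shared regions with the bootstrap SE, and the line is the 75th percentile of the local background at the same regions. The points of chromosome 16 all lie below 0 and those of chromosome 12 all above 0, and the lowest point, -1.11, is on chromosome 15.

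Dense groups of accessible regions, joined where neighbours lay within the stitching distance, were partly the same in both lines. Of the 200 groups with the highest summed fold enrichment, 55 of zcrest 1 (27.5%, exact binomial interval 21.4% to 34.2%) overlapped a top group of zcrest 2, where shifted lists gave a mean of 3.85 (permutation test with 1000 shifts, one-sided p = 0.001, the smallest they can give). With joining over 25 kb the overlap was 52 and the shifted mean 14.5, a smaller excess. The 5 groups of most regions included, in both lines, one on chromosome 16 at 20243779 to 20325310, with 30 regions in zcrest 1 and 30 in zcrest 2, and one on chromosome 8, at 36377472 to 36442810 with 28 regions in zcrest 1 and at 36353405 to 36443149 with 31 in zcrest 2. Both lay on a raised local background in both lines, 6.10 and 14.5 times the median in zcrest 1. That background counts the reads of the groups' own regions. The groups were picked for many regions, so a high value may partly follow from the choice. In zcrest 2 the group of most regions, 33, was on chromosome 24 at 12338431 to 12466977, where zcrest 1 had 22. Groups on chromosome 12 at 15425329 to 15480849 and on chromosome 10 at 16773673 to 16812601 followed, with 23 and 22 regions in zcrest 2 and 14 and 19 in zcrest 1.

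The 3 groups of most regions in zcrest 1 held 13, 2 and 5 regions in zcrest 2. The group on chromosome 15 at 37514648 to 37703772 held 33 regions, 20 of them in zcrest 1 alone. The group on chromosome 3 at 51069242 to 51242127 held 32 regions, all 32 in zcrest 1 alone, with the 2 regions of zcrest 2 more than 1 kb from any of them. The group on chromosome 2 at 20833190 to 21007884 held 31, of which 24 were in zcrest 1 alone. The local background in these groups was 3.31, 3.92 and 3.02 times the median in zcrest 1 and 0.694, 0.694 and 0.752 times the median in zcrest 2, where 0.694 is the genome-wide background, the lowest value possible. It counts the reads of a region and of its close neighbours, so a high value in groups picked for many regions may partly follow from the choice. In zcrest 2 it was taken at that line's own 13, 2 and 5 regions and not at matched ones. The test of shared groups was on the top 200 as a set, and the difference between the lines at any 1 group was not tested.

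**Figure D3:**
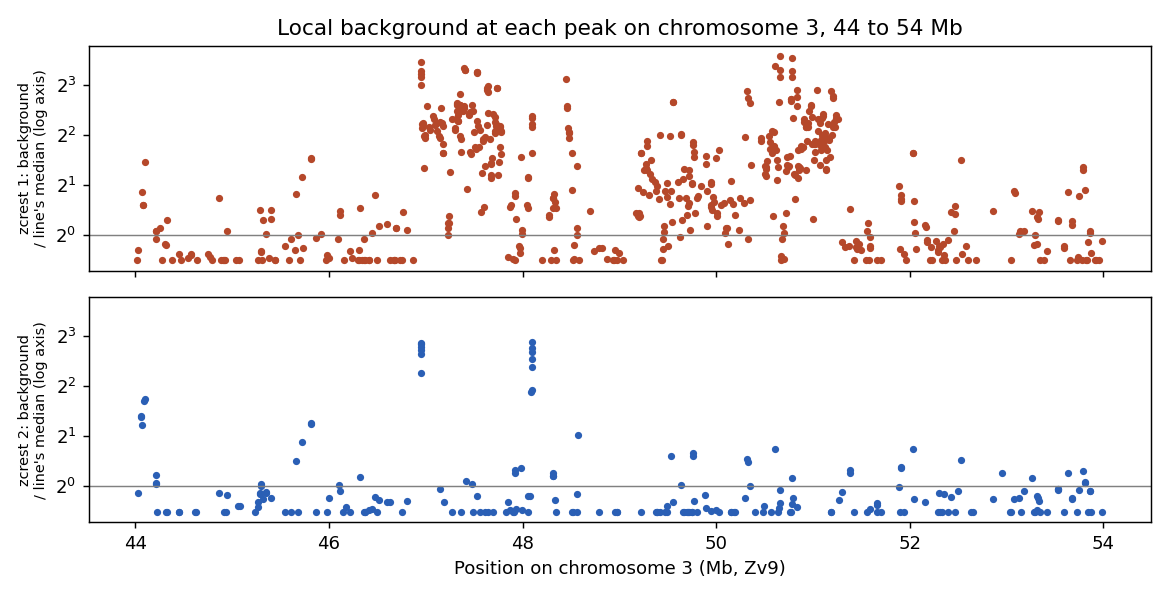
Local background at each accessible region of chromosome 3 from 44 to 54 Mb (x axis, Mb), divided by the line's median and drawn on a log axis, in zcrest 1 (red, top) and zcrest 2 (blue, bottom); each point is 1 region. In zcrest 1 the median was 4.26 between 47 and 48 Mb and 3.44 between 50.5 and 51.5 Mb, where zcrest 2 had 0.717 and 0.779.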

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

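Alternatives were planned except leaving out the windows of raised background and the variants of the pileup ratio, which were chosen after the result was seen. The share of shared peaks, 54.7% in zcrest 1 and 64.9% in zcrest 2, was 45.3% and 53.95% with a 50% reciprocal overlap, 41.3% and 49.3% with summits within 100 bp, 50.2% and 59.8% within 250 bp, and 58.4% and 69.2% for peaks within 1 kb. It was 55.9% and 69.8% at a -log10 q of at least 5, 53.7% and 71.4% at 10, 55.3% and 55.2% for the 10000 strongest peaks, and 60.2% and 60.2% with lists of equal length. The excess over shifted lists was 15.5 and 15.4 with local shifts (permutation p = 0.001), and at a -log10 q of at least 10 it was 28.1 and 27.8 (permutation p = 0.005, the smallest these fewer shifts can give). At that threshold 29005 and 21705 peaks were left, and 7033 and 2157 of them had no peak of any strength in the other line within 1 kb. Ranked by fold enrichment, the weakest decile was shared in 28.5% and 31.9% and the strongest in 85.4% and 96.3%. The rank correlation was 0.578 for -log10 q. The overlap of the top 200 clusters was 53 with joining over 5 kb, 52 over 25 kb and 55 ranked by number of peaks, but shifted lists gave a mean of 0.776, 14.5 and 3.54 (permutation p = 0.001 each), so the excess was smallest over 25 kb. Chromosomes that passed the test numbered 24 with any gap counted, 23 beyond 5 kb, 23 without the raised windows, and 16 at a -log10 q of at least 10, where fewer peaks were tested. In 90 of 100 chromosome settings the odds ratio kept its side of the threshold, and its direction except on chromosome 6, which did not pass and went from 1.01 to 0.969 beyond 5 kb. Of the others, 7 no longer passed, 2 newly passed (chromosome 14), and chromosome 25 reversed to 0.886 without passing. For the pileup ratio, 10 of 50 settings lay within the interval, 37 moved beyond it without a change of sign except chromosome 10 (-0.09 by background, from 0.01, within 2 SE of 0), and 3 near 0 reversed: chromosome 7 to 0.0915 with at least 60 reads per pair and to 0.0538 by background, and chromosome 14 to -0.0110 by background. The cause was not tested. The weakest decile rested on a median of 9 and 11 reads, and no setting varied the depth. The planned windows at transcript starts (annotation and gene lists) and around motifs were not run, and with 1 library per line no replicate could be left out.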

Other observations

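The test of library depth, the test of repeated sequence and both tests of the difference in peak number were chosen after the result was seen. So were the parts of chromosome 4, the stretches and the windows described here.

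Chromosome 4, whose long arm is rich in repeats and heterochromatin in zebrafish, had few accessible regions in both lines. Beyond 25 Mb it held 25.4 regions per Mb in zcrest 1 and 24.9 in zcrest 2, where the other chromosomes held 47.6 and 39.9. To 25 Mb the chromosome was as sparse, with 29.2 and 21.2 regions per Mb, so the low density was not particular to the part beyond 25 Mb. Regions beyond 25 Mb were shared less often than the 55.1% and 65.4% of the other chromosomes: 39.2% in zcrest 1 (exact binomial interval 36.1% to 42.4%) and 39.5% in zcrest 2 (36.3% to 42.7%). Matched on strength, 47.0% and 58.6% would be shared at the rate of the whole genome. To 25 Mb, 42.7% of the regions of zcrest 1 and 59.3% of those of zcrest 2 were shared, where 52.9% and 63.7% would be.

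In 9 windows of 500 kb the background was at least 3 times the median in both lines. Among them were chromosome 8 from 36 to 36.5 Mb, at 13.8 times the median in zcrest 1 and 14.5 in zcrest 2, and chromosome 10 from 16.5 to 17 Mb, at 13.7 and 10.9 times. By the median over each line's own regions, a further 10 windows passed in zcrest 1 alone and 11 in zcrest 2 alone, but these medians rest on different regions in each line. At regions matched one to one, the 11 windows of zcrest 2 did not stand apart: the median ratio of background, zcrest 2 over zcrest 1, was 0.745 to 1.24. The same held in zcrest 1 for chromosome 4 from 35.5 to 36 Mb (1.32) and chromosome 24 from 16 to 16.5 Mb (1.06). The ratio was 0.147 to 0.173 in the 3 windows of chromosome 2 from 20.5 to 22 Mb, 0.169 and 0.490 on chromosome 3 from 47 to 48 Mb, 0.115 from 50.5 to 51 Mb and 0.30 on chromosome 20 from 14 to 14.5 Mb. On chromosome 3 from 51 to 51.5 Mb it was 1.00, at only 2 matched regions, with neither line raised at them. The longest run of regions found in a single line, with no shared region between them, in zcrest 1 was 67 regions on chromosome 3 at 50838395 to 51261650, where the longest run among redrawn orders was 25. In zcrest 2 it was 21 regions on chromosome 5 at 74184001 to 74405650, against 18. Runs of 31, 29 and 24 regions in zcrest 1 lay close together on chromosome 15 at 38255735 to 38515402, 37334420 to 37515028 and 36974059 to 37319187, with a background 2.62, 2.09 and 1.87 times the median. The run of 24 did not exceed the longest redrawn run, 25. The next runs of zcrest 1 did not all lie on raised background. It was 5.10 times the median for 24 regions on chromosome 20, 1.05 and 0.902 for 24 and 23 on chromosome 7, and 0.996 for 22 on chromosome 9.

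The first pattern weighed is the broad difference between the lines along chromosomes. A single factor of library depth would leave the chromosomes alike, but 22 of 25 chromosomes lay over 2 bootstrap SE from the genome-wide ratio. Counting noise would not make neighbours alike, and the correlation of neighbouring 5-Mb windows was 0.76, where the highest of 10000 permuted orders reached 0.23 and of orders within chromosomes 0.62 (permutation p = 0.0001, the smallest they can give). DNA copy number and accessibility of the peaks alone stay open: at peaks with no other within 5 kb, background with the peak's own reads subtracted moved with pileup across chromosomes with a slope of 0.508 (SE 0.10, Pearson r 0.72 and Spearman rho 0.66, permutation p = 4e-05 and 0.00042, 0.74 without the 2 farthest chromosomes), which reaches the 0.5 set for copy number by less than its error, and less 2 SE is 0.303, above the 0.25 set for accessibility alone. Accessibility alone was set to be rejected only where the slope less 2 SE reached 0.5, which 0.303 did not. By the limits set, neither explanation was decided, and the 2 cannot be told apart here. This background had a log2 ratio of -0.01 (bootstrap SE 0.06) on chromosome 16 and 0.05 (SE 0.05) on chromosome 15, where pileup had -0.55 and -0.30. On chromosome 18 it had 0.57 (SE 0.03), where pileup had 0.36. It was measured at each line's own isolated shared peaks, 567 and 700 on chromosome 16, and not at matched pairs. Own reads were taken as summit pileup over the full width, which can subtract too much. Of these peaks, 27.6% and 26.9% lay at the genome-wide value. At matched pairs, own reads included, background had -0.78 on chromosome 16 and -0.59 on chromosome 15. A bias from base composition was not tested.

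The second pattern is the stretches of at least 2 adjacent windows raised in zcrest 1 alone, on chromosome 2 from 20.5 to 22 Mb and chromosome 3 from 47 to 48 and from 50.5 to 51.5 Mb. They held 416 regions of zcrest 1, 334 of them in that line alone, and 88 of zcrest 2, and at 69 regions matched one to one the median background was 5.35 times that of the genome in zcrest 1 and 0.786 times in zcrest 2. Sequence repeated or collapsed in the assembly would raise both lines if both carried the same number of copies, which was not measured. Although the stretches were picked as under 3 times the median in zcrest 2, its background there was far below even that, at 0.755 times its median (quartiles 0.694, the lowest value possible, and 1.03). At 138 regions with no other called region within 5 kb, the background, own reads subtracted, was 3.86 times that of such regions elsewhere (quartiles 1.44 and 5.14). Reads of called neighbours were not in the windows of these 138. For the other regions of the stretches, such reads are not excluded as a cause. The ratio at the 138 may also be high by selection, since the 138 are among the regions by whose background the stretches were picked. Accessible sites below the calling threshold were also not seen. A focal gain of DNA in zcrest 1 is a candidate explanation and a hypothesis only, since it was found and tested on the same data and no measure of DNA alone was used here.

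The third pattern is that the library of higher background, zcrest 2, had fewer regions. A stricter q-value threshold in zcrest 2 is argued against, since the lowest -log10 q of the lists differed by 0.011. This does not show that calling was equally strict in reads, since the same threshold can ask for more reads over a higher background. On the numbered chromosomes the lowest summit pileup was 7 in zcrest 1 and 8 in zcrest 2. At shared regions the summit pileup in zcrest 2 was 1.06 times that in zcrest 1, while the genome-wide background was 1.28 times as high. A lower share of reads in accessible regions in zcrest 2 may therefore account for the difference, and whether it came from the line or from the preparation of the library was not tested and no replicate separates them.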
